A study of Ambystoma mexicanum with 15 samples.

How the data were processed

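Total RNA from axolotl (Ambystoma mexicanum) spinal cord tissue was measured on 15 Affymetrix custom axolotl arrays, each hybridized with RNA from tissue of 10 pooled animals. Per the labels, RNA was extracted with Trizol and biotin-labelled with a 3' IVT kit. The labels placed the arrays in 5 groups of 3: uninjured, 1, 3 and 7 days after injury, and ivermectin with sampling 1 day after injury. The authors processed the arrays with RMA (background correction, quantile normalization between arrays and summary over probes) in Affymetrix Expression Console, and the deposited values were log2 expression values per probe set. Whether all 15 arrays were normalized together was not stated. The values were used as deposited. Array medians lay between 5.80 and 5.89, no value was missing, and a check for duplicated arrays found 0. No detection call was used, so a probe set near the lower quartile of its array was not shown to be above background. Among the named genes this holds, for example, for the uninjured levels of REG4, C1QTNF3, SLC13A3, SLC2A2, ALDH1B1, SCG3 and WNT2B, the ivermectin level of SCG3 and the 3 day levels of LEP and S100Z, and differences from such levels are not exact. Arrays carry no count depth, and the number of arrays limits the precision.

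Of 20080 probe sets, 45 Affymetrix controls were set aside, which left 20035 for testing. A gene symbol was given for 10951 probe sets, which covered 8639 genes, and 9084 probe sets carried no name. For 1740 genes with several probe sets, the probe set with the highest mean over all arrays represented the gene. Positions in the genome were not used here. Among the controls, 24 probe sets for poly-A RNA added before labelling and 18 probe sets for hybridization controls were averaged per array.

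A linear model with 1 mean per group was fitted to all 15 arrays with limma 3.58.1 (lmFit and eBayes; statmod 1.5.0; R 4.3.3), with 10 residual degrees of freedom and 4.26 prior degrees of freedom. Each of 7 comparisons was tested 2-sided, with Benjamini-Hochberg adjustment over the 20035 probe sets, and an adjusted p under 0.05 is called changed. The replicates were pools, so the p-values rest on the spread between pools. Replicate numbers were checked for pairing over 30 pairs of arrays, with median residual correlation -0.0062, and were not used as a block.

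Sets of genes were tested with camera in limma, with a preset inter-gene correlation of 0.01, on 1 probe set per gene. The 31 lists were written from textbook knowledge before the data were examined, as were the 7 comparisons and the rule for naming genes. Adjustment ran over the 217 tests of lists and comparisons together. The same lists were tested with an estimated correlation and with fry, which tests whether a list's genes move one way on balance, or in its mixed form whether they move either way. A called list without a stated p for an estimated correlation passed with it too, but its p could be far larger. At 1 day against uninjured the adjusted p of camera with an estimated correlation was 0.00266 for skeletal muscle genes. It was 0.00167 for G2 and M phase genes and 0.00268 for S phase genes. The preset correlation gave 1.14e-19, 4.88e-16 and 2.54e-14. Counts of members are given over all probe sets tested and adjusted over the list alone.

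In the 4 main comparisons (1, 3 and 7 days against uninjured, and ivermectin against 1 day), the named genes are the 8 with the largest rise and the 8 with the largest fall among named genes past the threshold whose arrays did not overlap between groups. Up to 4 members with the largest change come from each list described, plus FOS, JUN, GFAP, VIM, PCNA, MKI67, CCNB1, MMP9 and MBP in every comparison. SOX2 and SNAP25 were in the rule and had no named probe set. Any gene named outside this rule is marked as chosen after its values were seen. Without any effect, no overlap between 3 and 3 arrays has a chance of 10%.

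Comparisons that share a group are not independent, so correlations between them stand beside values from 100 simulations with no effect. The pipeline was tested on simulated data, in which 91% to 100% of 67 probe sets shifted by 0.5 on the log2 scale were recovered, depending on the comparison, with 9 to 20 false calls. Alternatives were a replicate block, a fit of the compared groups alone, an intensity trend of the prior variance, cyclic loess, median centring, dim probe sets left out (lowest 25%), a log2 change of at least 1, a test with unequal variances, array weights, genes instead of probe sets, the mean of a gene's probe sets for the lists, and leaving out each array. Lists of kidney, liver and intestinal genes were compared with 10000 random lists of matched mean expression. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.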

Results

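Gene expression was measured in axolotl spinal cord, an organ that regenerates after injury, without injury, at 1, 3 and 7 days after removal of a piece of the cord, and at 1 day after the same injury with ivermectin. Ivermectin opens ligand-gated chloride channels and acts on other ligand-gated channels, and was injected into the central canal before the injury. Each of the 5 groups had 3 arrays, each from a pool of 10 animals. The labels give an age of 1 month in every group, describe only the uninjured tissue as mature, and do not state how much surrounding tissue was taken. Values are log2 expression per probe set, and fold changes are log2 differences ± SE from limma (n = 3 arrays per group).

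The ivermectin arrays lay next to the uninjured arrays. Between these groups the correlation across probe sets was 0.996 to 0.997, against 0.967 to 0.968 between ivermectin and 1 day arrays, both 1 day after injury. Within groups it was 0.997 to 0.999 (probe sets are not independent replicates). The first principal component held 66.5% of the variance and the second 16.7%. Poly-A control RNA, added in the laboratory before labelling, read 7.54 ± 0.0286 (SD, n = 3) in uninjured arrays and 7.43 ± 0.0475 in ivermectin arrays. It read 8.08 ± 0.0441 at 1 day, 8.33 ± 0.0955 at 3 days and 7.94 ± 0.140 at 7 days. The labels name no processing batch. The arrays divide on this control along group lines, so no comparison across the division can be recomputed within 1 side. Ivermectin against uninjured, 3 days against 1 day and 7 days against 3 days lie within a side. These comparisons are not free of a difference in the control, since the arrays of the compared groups did not overlap on it. Within the 1, 3 and 7 day arrays it spanned 0.603, against a gap of 0.630 between the means of the sides.

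**Figure D1:**
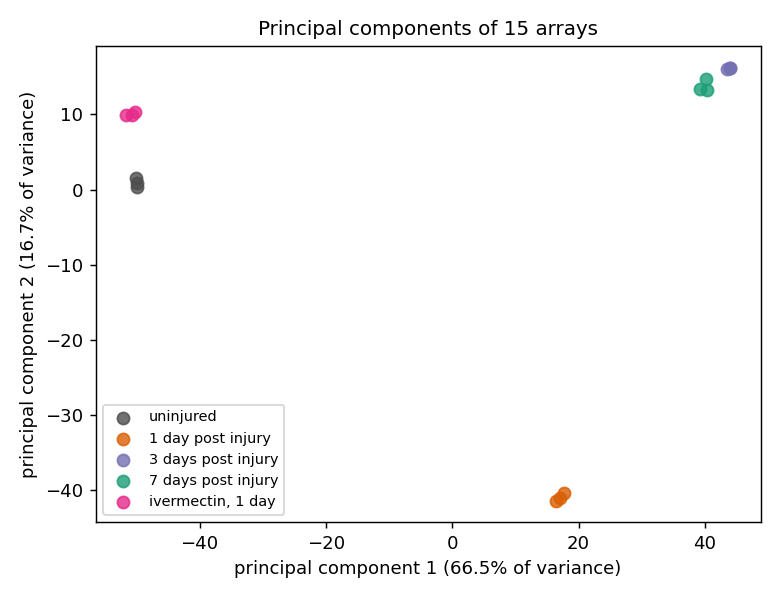
Principal components of the 15 arrays over 20035 probe sets, each point 1 array, the axes in component scores with the share of variance (66.5% and 16.7%). Uninjured and ivermectin arrays lie at the left, apart from the 1 day arrays and from the 3 and 7 day arrays.

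**Figure D2:**
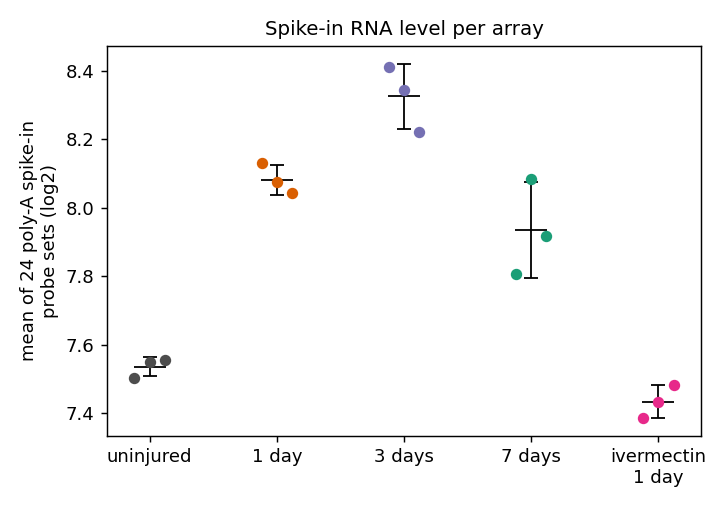
Mean log2 level of 24 poly-A control probe sets per array (points), with the group mean and SD (lines, n = 3). Every 1, 3 and 7 day array lies at 7.81 or above and every uninjured and ivermectin array at 7.56 or below.

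The comparison of 1 day after injury with uninjured cord asks which genes respond early. At 1 day the early response transcription factor FOS (probe set axo10931-f_at) rose by 2.65 ± 0.07 (6.29-fold), and NFKBIA, an inhibitor and target of NF-kB, rose by 1.82 ± 0.06. DDIT4, which restrains mTOR signalling, rose by 2.79 ± 0.08 and the glucose transporter SLC2A1 by 2.40 ± 0.06. CCNB1, the cyclin that drives entry into mitosis, changed by -2.51 ± 0.06 (5.68-fold lower). Markers of skeletal muscle, extracellular matrix and motile cilia rose, and cell cycle genes fell.

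Of the 16 measured immediate early genes, 9 rose and 2 fell (the same counts adjusted over the list alone), with median log2 change 0.38 and adjusted p = 0.00985. FOS, the mRNA decay factor ZFP36 (1.96 ± 0.22) and the MAP kinase phosphatase DUSP1 (1.70 ± 0.08) were among the 9, and MYC fell by 1.04 on the log2 scale. JUN differed by -0.09 ± 0.07 (adjusted p = 0.273). Inflammatory and NF-kB target genes rose in 9 of 16 cases and fell in 2, the same adjusted over the list alone (adjusted p = 0.0104; adjusted p = 0.0851 with an estimated correlation). They included the cytokine signalling inhibitor SOCS1 (0.93 ± 0.05) and the prostaglandin synthase PTGS2 (0.88 ± 0.24). Among 23 extracellular proteases and their inhibitors, 13 rose and 3 fell, as they did adjusted over the list alone (adjusted p = 0.0122). The matrix metalloproteinases MMP19 (1.12 ± 0.07) and MMP2 (1.08 ± 0.05) and the inhibitor TIMP1 (1.04 ± 0.04) rose, whereas MMP9 differed by 0.03 ± 0.14 (adjusted p = 0.868). Glycolysis and hypoxia genes rose in 17 of 28 cases and fell in 3 (17 and 4 adjusted over the list alone; adjusted p = 0.000441), among them the heme oxygenase HMOX1 (1.38 ± 0.04).

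Cell cycle genes fell at 1 day. Of 58 G2 and M phase genes, 53 fell and 1 rose (55 and 2 adjusted over the list alone), with median log2 change -0.79 and adjusted p = 4.88e-16. The mitotic kinases AURKA (-2.12 ± 0.06) and PLK1 (-1.84 ± 0.06) were among them. Of 47 S phase genes, 42 fell and 0 rose by limma, the same adjusted over the list alone (median -0.64, adjusted p = 2.54e-14), including the thymidine kinase TK1 (-2.47 ± 0.09) and UHRF1, which maintains DNA methylation (-1.57 ± 0.05). The proliferation markers PCNA (-0.50 ± 0.05) and MKI67 (-0.44 ± 0.07) fell less. Cholesterol synthesis genes fell in 13 of 20 cases and rose in 1, as they did adjusted over the list alone (adjusted p = 0.000778), among them the synthases FDPS (-1.93 ± 0.06) and HMGCS1 (-1.08 ± 0.06). INSIG1, which regulates sterol synthesis, fell by 2.32 on the log2 scale. Heat shock and unfolded protein response genes fell in 20 of 37 cases and rose in 8 (20 and 9 adjusted over the list alone; adjusted p = 0.0406; adjusted p = 0.102 with an estimated correlation). The endoplasmic reticulum chaperone HSPA5 fell by 1.13 on the log2 scale.

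Skeletal muscle genes rose in 51 of 55 cases and fell in 1, both unchanged adjusted over the list alone (median 0.70, adjusted p = 1.14e-19). The myosin-binding protein MYBPC1 rose by 3.63 ± 0.08 and the sarcomeric actinin ACTN2 by 3.46 ± 0.09. Structural matrix genes rose in 34 of 48 cases and fell in 5, the same adjusted over the list alone (adjusted p = 2.00e-11). They included the nervous system proteoglycan BCAN (2.73 ± 0.05), the laminin chain LAMA2 (1.63 ± 0.10) and the collagen COL5A2 (1.59 ± 0.08). The fibrillin FBN1 rose by 3.37 ± 0.08, although another of its probe sets was called the opposite way. Motile cilia genes, which ependymal cells express, rose in 33 of 43 cases and fell in 0 by limma (34 and 0 adjusted over the list alone; adjusted p = 1.96e-11), among them the tektins TEKT4 (2.11 ± 0.07) and TEKT2 (1.96 ± 0.08). Neuronal genes rose in 29 of 49 cases and fell in 1, the same adjusted over the list alone (adjusted p = 1.06e-06), with the secretory granule protein SCG3 at 2.06 ± 0.09 and the growth cone protein GAP43 at 1.10 ± 0.09. Of 38 neurotransmitter receptors and transporters, 13 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 0.0267), with the glutamate receptor subunit GRIK2 at 1.44 ± 0.05.

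Red cell genes rose in 9 of 12 cases and fell in 0 by limma (10 and 0 adjusted over the list alone; adjusted p = 6.70e-05), among them the heme synthesis enzyme ALAS2 (1.62 ± 0.06). Of 24 myelin genes 12 rose and 4 fell (adjusted p = 0.0411; adjusted p = 0.121 with an estimated correlation). Among 47 channels and pumps, 14 rose and 3 fell (adjusted p = 0.0370; adjusted p = 0.109 with an estimated correlation). Epidermal genes fell in 9 of 19 cases and rose in 3 (adjusted p = 0.0316; adjusted p = 0.210 with an estimated correlation). In these 3 lists the counts were the same adjusted over the list alone. Of 34 ependymoglial genes 11 rose and 7 fell, the same adjusted over the list alone, and the list was not called (adjusted p = 0.489). Its members GFAP and VIM, intermediate filament proteins of ependymoglia, rose by 0.62 ± 0.05 and 0.42 ± 0.04, and the myelin protein MBP by 0.67 ± 0.05.

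In all, 5024 of the 20035 probe sets rose and 5762 fell at 1 day, 1426 of them by at least 2-fold. The balance reversed with cyclic loess (5615 rose, 5163 fell) and with median centring (5737 and 5182). The largest rises were those of TCEA2, a transcription elongation factor (3.94 ± 0.11), PMCH, the precursor of melanin-concentrating hormone (3.80 ± 0.11), and the secreted protein C1QTNF3 (3.67 ± 0.08), with MYBPC1, ACTN2, FBN1 and the cadherins CDH17 (3.37 ± 0.06) and CDH13 (2.81 ± 0.08). The largest falls were those of the serine synthesis enzyme PSAT1 (-3.01 ± 0.05), NCOA7 (-2.78 ± 0.08), the RNA-binding protein ILF2 (-2.57 ± 0.05), CCNB1, TK1, INSIG1, S100Z (-2.20 ± 0.19) and the RNA exosome subunit EXOSC2 (-2.18 ± 0.06). The poly-A control was 0.546 higher in the 1 day arrays than in the uninjured arrays.

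**Figure D3:**
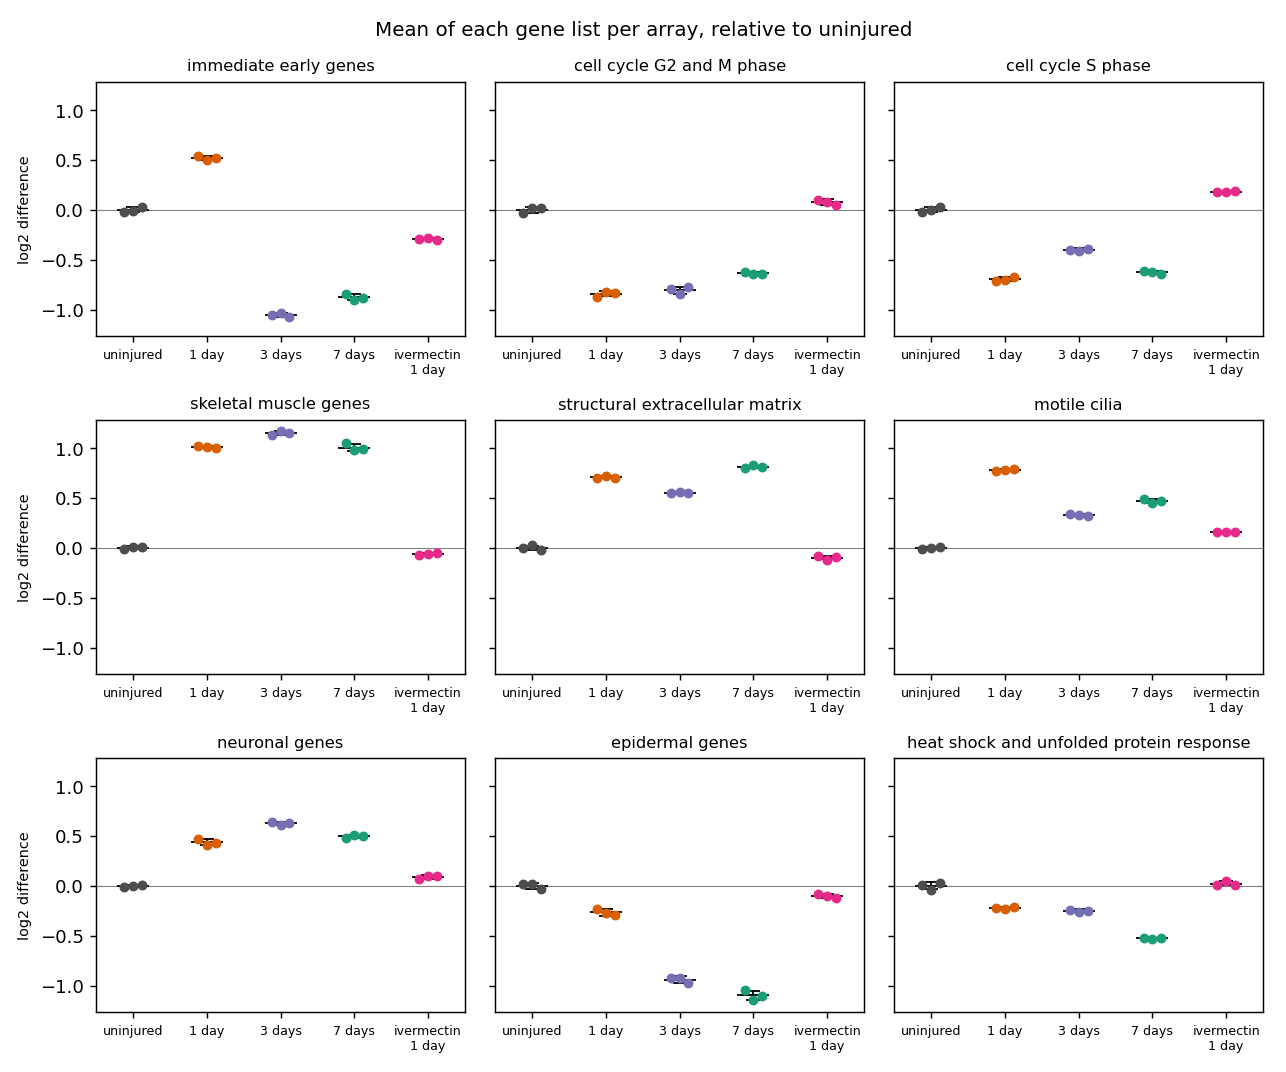
Mean of each of 9 gene lists per array, as log2 difference from the uninjured mean (points are arrays, lines the group mean and SD, n = 3). Immediate early genes lie above uninjured at 1 day and below at 3 and 7 days, and cell cycle lists lie below uninjured at 1, 3 and 7 days and not in the ivermectin arrays.

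The comparison of 3 days with uninjured cord follows the response later. At 3 days the secreted lectin REG4 (probe set axo06955-r_at) rose by 8.27 ± 0.08, from 4.35 ± 0.131 to 12.62 ± 0.0293 (SD, n = 3). The cadherin CDH17 rose by 5.82 ± 0.06 and RGN, a calcium-binding gluconolactonase, by 5.81 ± 0.07. Immediate early genes, raised at 1 day, were below uninjured cord. Muscle, matrix and neuronal genes remained higher as lists, and cell cycle genes lower.

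Immediate early genes fell in 12 of 16 cases and rose in 1, the same adjusted over the list alone (median -0.99, adjusted p = 2.74e-05). FOS changed by -2.40 ± 0.07, MYC by -2.03 ± 0.07, JUNB by -1.95 ± 0.09, and the transcription factor KLF2 by -1.85 ± 0.05. Feedback genes of the ERK pathway fell in 8 of 13 cases and rose in 3, as they did adjusted over the list alone (adjusted p = 0.0182). The epidermal growth factor receptor ligand AREG (-3.38 ± 0.05) and the phosphatase DUSP5 (-2.48 ± 0.08) were among the 8. Inflammatory genes fell in 10 of 16 cases and rose in 4, the same adjusted over the list alone (adjusted p = 0.0398; adjusted p = 0.142 with an estimated correlation), with NFKBIA at -2.03 ± 0.06. Of 22 apoptosis and p53 genes 15 fell and 2 rose, unchanged adjusted over the list alone (adjusted p = 0.00193), among them the growth arrest gene GADD45A (-1.66 ± 0.06) and MDM2, which restrains p53 (-1.50 ± 0.10). Interferon response genes fell in 8 of 13 cases and rose in 2, unchanged adjusted over the list alone (adjusted p = 0.0395; adjusted p = 0.128 with an estimated correlation), with IRF1 at -1.32 ± 0.05.

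Of 58 G2 and M phase genes 51 fell and 2 rose (51 and 3 adjusted over the list alone; median -0.82, adjusted p = 1.31e-12), led by AURKA (-1.74 ± 0.06) and the anaphase activator CDC20 (-1.65 ± 0.05). Of 47 S phase genes 34 fell and 2 rose (34 and 3 adjusted over the list alone; adjusted p = 1.97e-06), with TK1 at -1.89 ± 0.09. CCNB1 fell by 1.43 on the log2 scale and PCNA by 0.32, and MKI67 differed by 0.15 ± 0.07 (adjusted p = 0.0589). Epidermal genes fell in 17 of 19 cases and rose in 0 by limma, the same adjusted over the list alone (median -0.75, adjusted p = 4.09e-07). GRHL3 (-2.36 ± 0.06) and TP63 (-1.96 ± 0.11), transcription factors of epidermis, and the crosslinking enzyme TGM1 (-1.88 ± 0.05) were among them. Cartilage and bone genes fell in 13 of 24 cases and rose in 3 (14 and 4 adjusted over the list alone; adjusted p = 0.00773; adjusted p = 0.101 with an estimated correlation), with the matrilin MATN3 at -2.74 ± 0.08. Cholesterol synthesis genes fell in 12 of 20 cases and rose in 5 (adjusted p = 0.0294; adjusted p = 0.0580 with an estimated correlation), with FDPS at -2.29 ± 0.06. Heat shock and unfolded protein response genes fell in 19 of 37 cases and rose in 7 (adjusted p = 0.0370; adjusted p = 0.0973 with an estimated correlation), with the stress transcription factor DDIT3 at -2.43 ± 0.05. Both lists gave the same counts adjusted over the list alone.

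Skeletal muscle genes rose in 49 of 55 cases and fell in 2, unchanged adjusted over the list alone (median 1.03, adjusted p = 6.62e-18), among them MYBPC2 (3.28 ± 0.06) and the troponin TNNC1 (2.86 ± 0.05). Neuronal genes rose in 37 of 49 cases and fell in 1 (38 and 1 adjusted over the list alone; adjusted p = 3.02e-08), with the microtubule regulator STMN4 at 2.29 ± 0.07. Matrix genes rose in 33 of 48 cases and fell in 8 (35 and 8 adjusted over the list alone; adjusted p = 1.73e-06), with LAMA2 at 2.47 ± 0.10. Red cell genes rose in 11 of 12 cases and fell in 0 by limma (adjusted p = 9.71e-05), with the erythroid factor NFE2 at 1.84 ± 0.06. Cilia genes rose in 23 of 43 cases and fell in 2 (adjusted p = 0.000441), with TEKT2 at 0.88 ± 0.08. Glycolysis and hypoxia genes rose in 18 of 28 cases and fell in 4 (adjusted p = 0.00127), with the hypoxia-induced NDRG1 at 3.00 ± 0.08, while SLC2A1 fell by 1.76 on the log2 scale. Neurotransmitter receptors and transporters rose in 15 of 38 cases and fell in 1 (adjusted p = 0.0189). In these 4 lists the counts were the same adjusted over the list alone. Oxidative phosphorylation genes rose in 26 of 45 cases and fell in 5, the same adjusted over the list alone (adjusted p = 0.00259; adjusted p = 0.396 with an estimated correlation). Channels and pumps rose in 19 of 47 cases and fell in 6 (19 and 5 adjusted over the list alone; adjusted p = 0.0480; adjusted p = 0.127 with an estimated correlation). The ependymoglial list was not called, with 14 of 34 genes higher and 10 lower (15 and 10 adjusted over the list alone; adjusted p = 0.702). GFAP fell by 0.31 on the log2 scale, VIM rose by 0.32 ± 0.04 and MBP by 1.23 ± 0.05, and MMP9 differed by 0.10 ± 0.14 (adjusted p = 0.550).

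In all, 5962 probe sets rose and 6054 fell at 3 days, 2182 of them by at least 2-fold. The balance reversed with cyclic loess (6016 rose, 5939 fell) and with median centring (7623 and 5226). Other large rises were those of the dicarboxylate transporter SLC13A3 (4.95 ± 0.10), the oxysterol hydroxylase CYP7B1 (4.32 ± 0.07), the aldehyde dehydrogenase ALDH1B1 (4.14 ± 0.09), the glucose transporter SLC2A2 (3.95 ± 0.08) and C1QTNF3 (3.84 ± 0.08). The largest falls were those of the protease RHBDL2 (-3.87 ± 0.09), the tight junction protein CLDN3 (-3.70 ± 0.07), the nuclease DNASE1L3 (-3.69 ± 0.08), S100Z (-3.60 ± 0.19), AREG, PHLDA2 (-3.32 ± 0.10), the corneal proteoglycan KERA (-3.30 ± 0.11) and leptin, LEP (-3.26 ± 0.06). Another probe set of DNASE1L3 was called the opposite way. In uninjured arrays REG4 (4.35), C1QTNF3 (4.16), ALDH1B1 (3.95), SLC13A3 (3.66) and SLC2A2 (3.25) lay near or below the lower quartile of all probe sets (4.22 to 4.25), so these probe sets were not shown to be above background and their fold changes and ranks are not exact. The poly-A control was 0.789 higher at 3 days than in uninjured arrays.

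At 7 days against uninjured cord, which shows what persists, REG4 was still 7.21 ± 0.08 higher and RGN 5.01 ± 0.07 higher. Structural matrix genes were raised, with the nervous system proteoglycan BCAN at 3.16 ± 0.05. GFAP rose by 0.84 ± 0.05 and VIM by 0.65 ± 0.04. The chaperone HSPA5 fell by 3.04 on the log2 scale and the growth factor AREG by 3.88.

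Structural matrix genes rose in 37 of 48 cases and fell in 4, the same adjusted over the list alone (median 0.84, adjusted p = 1.39e-09). COL5A2 rose by 1.80 ± 0.08, and fibronectin, FN1, by 2.02 ± 0.06, with another FN1 probe set called the opposite way. Skeletal muscle genes rose in 48 of 55 cases and fell in 1 (adjusted p = 1.04e-15), with the ubiquitin ligase TRIM63 at 2.93 ± 0.13. Cilia genes rose in 30 of 43 cases and fell in 0 by limma (adjusted p = 1.56e-05), with TEKT4 at 1.19 ± 0.07. In both lists the counts were the same adjusted over the list alone. Neuronal genes rose in 23 of 49 cases and fell in 1 (22 and 1 adjusted over the list alone; adjusted p = 0.000347), with the RNA-binding protein ELAVL2 at 2.51 ± 0.07, STMN4 at 2.15 ± 0.07 and GAP43 at 1.73 ± 0.09. Endothelial and mural genes rose in 10 of 21 cases and fell in 2, unchanged adjusted over the list alone (adjusted p = 0.0168; adjusted p = 0.0764 with an estimated correlation), led by the smooth muscle gene TAGLN (3.56 ± 0.06). Glycolysis and hypoxia genes rose in 15 of 28 cases and fell in 5 (16 and 5 adjusted over the list alone; adjusted p = 0.0395; adjusted p = 0.110 with an estimated correlation), with the mitophagy receptor BNIP3 at 1.56 ± 0.06. The ependymoglial list had 15 of 34 genes higher and 8 lower (17 and 8 adjusted over the list alone) and was not called (adjusted p = 0.123), with the Notch target HEY1 at 1.73 ± 0.07. The neutrophil and macrophage list had 14 of 33 genes higher and 8 lower, the same adjusted over the list alone, and was not called (adjusted p = 0.244), with the complement gene C1QB at 2.13 ± 0.08.

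Epidermal genes fell in 17 of 19 cases (median -1.10, adjusted p = 2.61e-09), with GRHL3 at -2.57 ± 0.06. Immediate early genes fell in 14 of 16 cases (adjusted p = 7.89e-06), among them FOS (-1.45 ± 0.07), JUNB (-1.59 ± 0.09) and EGR1 (-1.29 ± 0.06). S phase genes fell in 42 of 47 cases (median -0.52, adjusted p = 1.35e-11), with the replication helicase subunit MCM7 at -1.34 ± 0.05. None of the 3 lists had a member that rose by limma, and the counts were the same adjusted over the list alone. G2 and M phase genes fell in 49 of 58 cases and rose in 3 (50 and 3 adjusted over the list alone; median -0.67, adjusted p = 1.75e-11), with PLK1 at -1.44 ± 0.06. Heat shock and unfolded protein response genes fell in 26 of 37 cases and rose in 5 (adjusted p = 9.35e-05), among them the co-chaperone DNAJB9 (-2.26 ± 0.06) and DDIT3 (-2.07 ± 0.05). ERK feedback genes fell in 8 of 13 cases and rose in 3 (adjusted p = 0.00754), with the receptor ligand EREG at -3.13 ± 0.05. Cholesterol synthesis genes fell in 12 of 20 cases and rose in 2 (adjusted p = 0.0123), with FDPS at -1.86 ± 0.06. Apoptosis and p53 genes fell in 12 of 22 cases and rose in 4 (adjusted p = 0.0311; adjusted p = 0.0580 with an estimated correlation), with MDM2 at -1.61 ± 0.10. In these 4 lists the counts were the same adjusted over the list alone. CCNB1 fell by 0.83 on the log2 scale, PCNA by 0.68, JUN by 0.41 and MBP by 0.14. MKI67 differed by -0.07 ± 0.07 (adjusted p = 0.384) and MMP9 by 0.01 ± 0.14 (adjusted p = 0.963).

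In all, 5761 probe sets rose and 5792 fell at 7 days, 2104 of them by at least 2-fold. With cyclic loess 5740 rose and 5888 fell, and with median centring 6349 and 5279. Large rises included C1QTNF3 (4.64 ± 0.08), CDH17 (4.41 ± 0.06), TCEA2 (4.16 ± 0.11), FBN1 (3.60 ± 0.08; another probe set called the opposite way) and SLC13A3 (3.22 ± 0.10). Large falls included PSAT1 (-4.07 ± 0.05), the keratinocyte exonuclease TREX2 (-3.81 ± 0.08), the joint lubricant PRG4 (-3.70 ± 0.08), PHLDA2 (-3.37 ± 0.10), CLDN3 (-3.35 ± 0.07) and S100Z (-3.28 ± 0.19). The poly-A control was 0.400 higher at 7 days than in uninjured arrays.

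**Figure D4:**
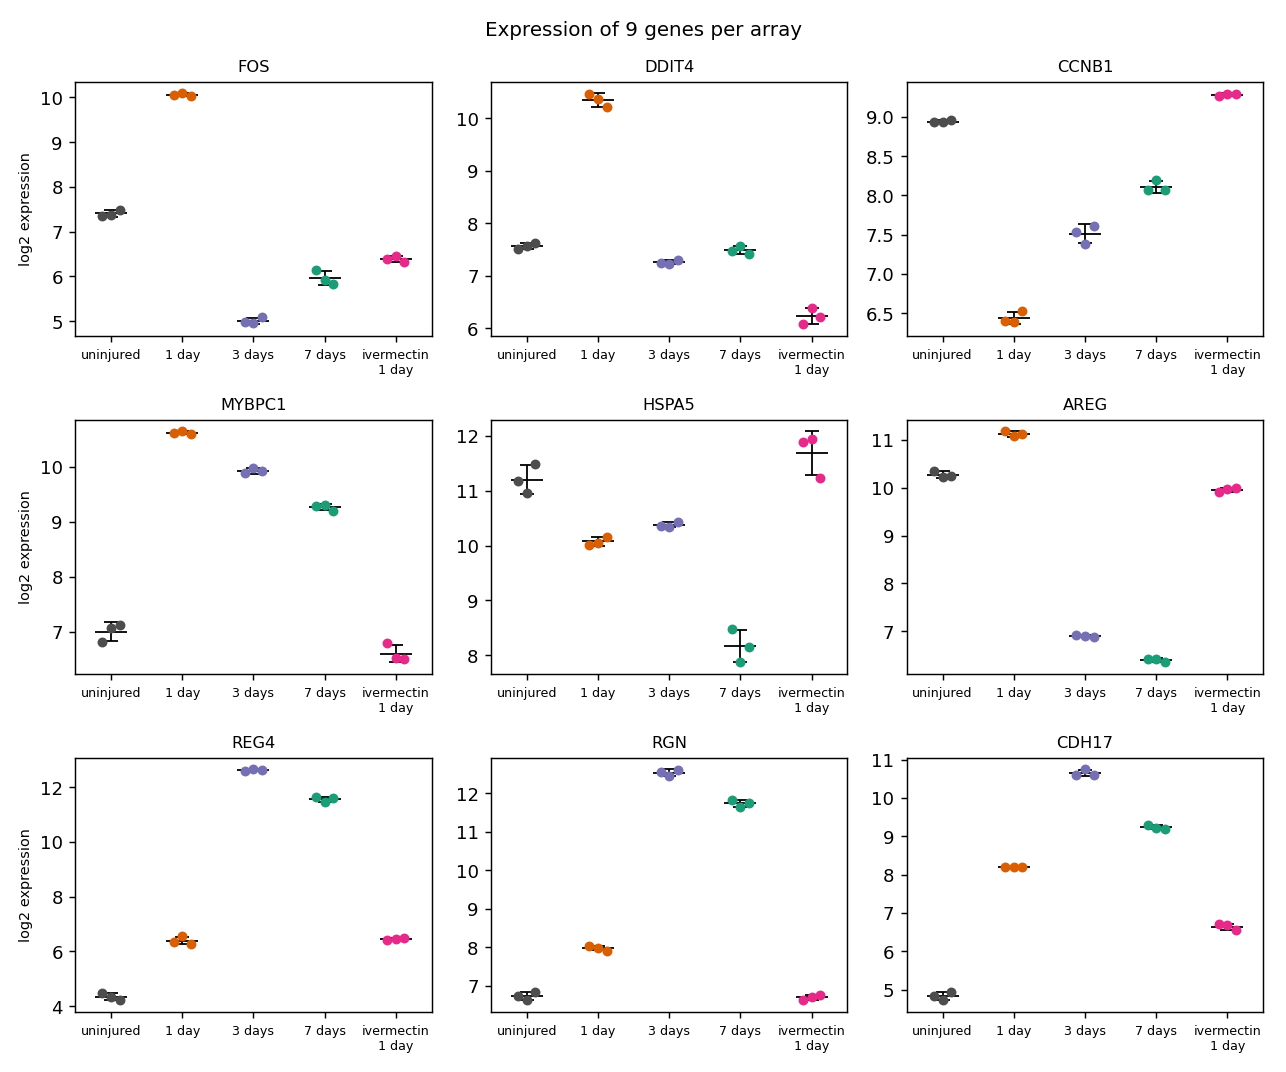
Log2 expression of 9 genes per array (points), with the group mean and SD (lines, n = 3); the vertical axes differ and do not start at 0. REG4, RGN and CDH17 are highest at 3 days, and FOS, DDIT4, MYBPC1 and AREG are highest at 1 day.

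Ivermectin against 1 day after injury asks what the drug changes early, in a series whose stated interest is membrane depolarization in the ependymoglial response. The labels do not say whether the 1 day animals were injected with vehicle. In the ivermectin arrays DDIT4 was 4.12 lower on the log2 scale (-4.12 ± 0.08, 17.4-fold), FOS changed by -3.68 ± 0.07 and SLC2A1 by -3.56 ± 0.06. Cell cycle genes were higher, with CCNB1 at 2.85 ± 0.06 (7.22-fold) and AURKA at 2.53 ± 0.06. Muscle, matrix and cilia genes were lower, with MYBPC1 at -4.02 ± 0.08.

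Of 58 G2 and M phase genes 55 rose and 2 fell, the same adjusted over the list alone (median 0.81, adjusted p = 8.43e-16). Of 47 S phase genes 44 rose and 0 fell by limma, unchanged adjusted over the list alone (median 0.79, adjusted p = 8.43e-16), among them TK1 (2.68 ± 0.09) and UHRF1 (2.00 ± 0.05). Cholesterol synthesis genes rose in 12 of 20 cases and fell in 1, unchanged adjusted over the list alone (adjusted p = 0.00102), with INSIG1 at 2.92 ± 0.09 and FDPS at 2.11 ± 0.06. PCNA rose by 0.73 ± 0.05 and MKI67 by 0.52 ± 0.07. Immediate early genes fell in 10 of 16 cases and rose in 2, the same adjusted over the list alone (median -0.56, adjusted p = 0.000553), with DUSP1 at -2.49 ± 0.08 and ZFP36 at -2.15 ± 0.22. Inflammatory genes fell in 11 of 16 cases and rose in 2 (12 and 2 adjusted over the list alone; adjusted p = 0.000835), with NFKBIA at -2.54 ± 0.06 and SOCS1 at -1.30 ± 0.05. Proteases and inhibitors fell in 13 of 23 cases and rose in 2, the same adjusted over the list alone (adjusted p = 0.00228), with MMP2 at -2.07 ± 0.05 and TIMP1 at -1.87 ± 0.04. Glycolysis and hypoxia genes fell in 16 of 28 cases and rose in 2 (18 and 2 adjusted over the list alone; adjusted p = 0.000163), with HMOX1 at -1.92 ± 0.04.

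Skeletal muscle genes fell in 49 of 55 cases and rose in 2 (50 and 2 adjusted over the list alone; median -0.71, adjusted p = 2.36e-18). Matrix genes fell in 38 of 48 cases and rose in 2, unchanged adjusted over the list alone (adjusted p = 6.12e-13), with BCAN at -2.91 ± 0.05. Cilia genes fell in 32 of 43 cases (33 adjusted over the list alone; adjusted p = 5.09e-09), with TEKT4 at -1.49 ± 0.07. Neuronal genes fell in 24 of 49 cases and rose in 1 (23 and 1 adjusted over the list alone; adjusted p = 9.21e-05), with SCG3 at -2.15 ± 0.09. Red cell genes fell in 9 of 12 cases (10 adjusted over the list alone; adjusted p = 6.28e-05), with ALAS2 at -1.95 ± 0.06. Endothelial and mural genes fell in 8 of 21 cases and rose in 3 (10 and 3 adjusted over the list alone; adjusted p = 0.0275; adjusted p = 0.0974 with an estimated correlation), with TAGLN at -2.09 ± 0.06. The ependymoglial list was not called, with 9 of 34 genes higher and 11 lower, the same adjusted over the list alone (adjusted p = 0.613). GFAP fell by 0.18 on the log2 scale, VIM by 0.48, MBP by 0.68 and JUN by 0.27, and MMP9 differed by -0.08 ± 0.14 (adjusted p = 0.670). Channels and pumps were lower in 16 of 47 cases and higher in 3, the same adjusted over the list alone, and neurotransmitter receptors and transporters lower in 11 of 38 (8 adjusted over the list alone). Neither list was called (adjusted p = 0.0550 and adjusted p = 0.0581).

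In all, 5934 probe sets rose and 5090 fell with ivermectin, 1563 of them by at least 2-fold. The balance reversed with cyclic loess (5358 rose, 5721 fell) and with median centring (5267 and 6085). Large rises were also those of NCOA7 (2.99 ± 0.08), ILF2 (2.62 ± 0.05), EXOSC2 (2.41 ± 0.06) and PSAT1 (2.39 ± 0.05), and large falls those of FBN1 (-3.70 ± 0.08; another probe set called the opposite way), ACTN2 (-3.69 ± 0.09), TCEA2 (-3.63 ± 0.11) and PMCH (-3.53 ± 0.11). Across probe sets, the ivermectin changes and the 1 day changes correlated at -0.965, with covariance -0.329. The 1 day arrays enter both, and simulations without effect gave -0.509 and -0.00391. Of the 10786 probe sets changed at 1 day, 10658 (98.8%) moved back with ivermectin, against 74.5% in simulations, and 9487 passed the test in doing so. Of the 10786, 1163 also differed between ivermectin and uninjured arrays. The correlation and the move back restate that the ivermectin arrays lay next to the uninjured arrays, and do not show the cause. The poly-A control read 7.43 in ivermectin arrays and 8.08 in 1 day arrays.

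Set directly against uninjured cord, the injured ivermectin tissue differed in 1393 probe sets, 606 higher and 787 lower, 32 of them by at least 2-fold. Outside the fixed genes, the genes named for this comparison were chosen after their values were seen. REG4 rose by 2.10 ± 0.08 and CDH17 by 1.82 ± 0.06, both also raised at 1 day. GFAP rose by 0.44 ± 0.05, CCNB1 by 0.35 ± 0.06 and PCNA by 0.23 ± 0.05. FOS fell by 1.02 on the log2 scale, the glucose transporter SLC2A1 by 1.15, the opioid precursor PENK by 1.14 and JUN by 0.36. VIM (-0.07 ± 0.04, adjusted p = 0.423), MKI67 (0.08 ± 0.07, adjusted p = 0.610), MBP (-0.01 ± 0.05, adjusted p = 0.967) and MMP9 (-0.04 ± 0.14, adjusted p = 0.916) did not pass. The called lists moved by small medians. S phase genes rose in 16 of 47 cases and fell in 0 by limma (25 and 0 adjusted over the list alone; median 0.18, adjusted p = 1.27e-13), and cilia genes rose in 8 of 43 (12 adjusted over the list alone; median 0.13, adjusted p = 1.44e-05). Immediate early genes fell in 7 of 16 cases, the same adjusted over the list alone (median -0.19, adjusted p = 8.85e-08), and matrix genes in 8 of 48, the same adjusted over the list alone (median -0.09, adjusted p = 1.05e-05). In all 17 lists passed here, 12 of them with an estimated correlation. With a separate variance for each probe set, 22 probe sets passed, and with the 6 arrays alone 861 did. The count was 904 without uninjured replicate 2 and 916 without ivermectin replicate 2.

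From 1 to 3 days, 4383 probe sets rose and 3755 fell, 788 of them by at least 2-fold, and from 3 to 7 days 4448 rose and 3722 fell, 400 of them by at least 2-fold. With cyclic loess 3916 rose and 4156 fell, then 3862 and 4141, and with median centring 5114 and 3359, then 3886 and 4392. Apart from the fixed genes, those named here were chosen after their values were seen. From 1 to 3 days FOS fell by 5.06 on the log2 scale, AREG by 4.22 and NFKBIA by 3.85, while REG4 rose by 6.23 ± 0.08 and RGN by 4.56 ± 0.07. Of 16 immediate early genes 14 fell (adjusted p = 1.35e-11), and of 16 inflammatory genes 10 fell and 1 rose (adjusted p = 9.16e-06). Of 47 S phase genes 26 rose and 8 fell (28 and 8 adjusted over the list alone; adjusted p = 0.000110), with CCNB1 at 1.08 ± 0.06 and MKI67 at 0.60 ± 0.07. GFAP fell by 0.93 on the log2 scale. Of 45 oxidative phosphorylation genes 32 rose and 1 fell (35 and 1 adjusted over the list alone; adjusted p = 9.11e-08; adjusted p = 0.137 with an estimated correlation).

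From 3 to 7 days GFAP rose by 1.15 ± 0.05, VIM by 0.34 ± 0.04, the collagen protease CTSK by 1.92 ± 0.07 and the macrophage receptor SIGLEC1 by 1.79 ± 0.09, while HSPA5 fell by 2.21 on the log2 scale, ALAS2 by 2.11 and MBP by 1.38. Of 33 neutrophil and macrophage genes 20 rose and 2 fell (21 and 2 adjusted over the list alone; adjusted p = 0.000206). Matrix genes rose in 27 of 48 cases and fell in 4 (27 and 7 adjusted over the list alone; adjusted p = 0.000340). Cartilage and bone genes rose in 13 of 24 cases and fell in 1 (14 and 1 adjusted over the list alone; adjusted p = 0.000192). Of 37 heat shock and unfolded protein response genes 21 fell and 4 rose (adjusted p = 2.01e-05), and of 34 ependymoglial genes 17 rose and 3 fell (17 and 5 adjusted over the list alone; adjusted p = 0.0337; adjusted p = 0.177 with an estimated correlation). Where no other count is given in these last comparisons, it was the same adjusted over the list alone. With unequal variances per probe set, 4485 probe sets changed from 1 to 3 days and 3877 from 3 to 7 days.

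The injury comparisons share the uninjured arrays. Changes at 3 and 7 days correlated at 0.865 across probe sets, with covariance 0.404 (simulated 0.00328). Simulations without effect gave a mean correlation of 0.435 and a range of -0.567 to 0.916, which holds the observed value. Changes at 1 and 3 days correlated at 0.734 (simulated mean 0.439, range -0.282 to 0.936, which also holds the observed value), with covariance 0.288 (simulated 0.00327). Of the probe sets called in both, 4229 were higher and 4546 lower at 3 and 7 days, where 1714 and 1750 would arise independently. At 1 and 3 days 3691 were higher in both and 4434 lower in both, where 1495 and 1741 would arise independently. Simulations without effect gave a mean of 0.02 shared calls or fewer in each direction. They hold no changed probe sets, so this value does not measure how far shared arrays raise the overlap among called ones. The 3 uninjured arrays were not divided between comparisons, and part of the excess can come from sharing them.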

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

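The differences between list changes below were tested directly, in 1 comparison each. A list was flagged only if called in opposite directions in both comparisons and called in the direct one. Passing the direct test was thus a condition of entry and adds no support. The tests on the ivermectin arrays, the muscle dilution test, both epidermal tests and the count of tissue genes between the quartiles were chosen only after the result was seen.

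Immediate early genes were above uninjured at 1 day (median 0.375) and below at 3 days (median -0.994), with a direct difference of -1.09 from 1 to 3 days (adjusted p = 1.35e-11). Inflammatory and NF-kB target genes did the same, with a direct difference of -0.756 (adjusted p = 9.16e-06). The inflammatory calls against uninjured were lost with an estimated correlation (adjusted p = 0.0851 at 1 day and adjusted p = 0.142 at 3 days).

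For 10 lists the 1 day change and the ivermectin change, each against uninjured, had opposite signs. For skeletal muscle genes the ivermectin median was -0.0123, and its sign was lost without uninjured replicate 3. Ivermectin minus 1 day was -0.558 for immediate early genes, -0.569 for inflammatory genes, -0.454 for red cell genes, -0.319 for proteases and inhibitors, -0.826 for matrix genes, -0.712 for skeletal muscle genes and -0.307 for glycolysis and hypoxia genes. It was 0.792 for S phase genes, 0.808 for G2 and M phase genes and 0.375 for cholesterol synthesis genes. All 10 passed in the direct comparison, as the flagging rule required, the largest adjusted p being 0.00228 (proteases). With an estimated correlation the calls of ivermectin against uninjured were lost for red cell genes (adjusted p = 0.0973), G2 and M phase genes (adjusted p = 0.0737) and skeletal muscle genes (adjusted p = 0.242). The poly-A control lay above uninjured by 0.546 at 1 day, 0.789 at 3 days and 0.400 at 7 days.

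The ivermectin arrays lay next to the uninjured arrays. The share of the 1 day response kept with ivermectin was -0.0411, which restates the pattern and would follow alike from the drug or from a batch, so it lends neither support. The poly-A control of the 1, 3 and 7 day arrays was 0.63 above that of the other 6, so a processing batch along the same line, or a different mRNA content of the samples, cannot be told apart from it. The hybridization controls did not divide this way, with means of 10.59 in uninjured and 10.72 in ivermectin arrays. They read 10.75 at 1 day, 10.79 at 3 days and 10.41 at 7 days. Ivermectin arrays made from the uninjured pools and processed with them are argued against: the highest count over splits mixing the 6 arrays was 2, against 861 in the real split. Uninjured pools processed separately would give such counts too, so the splits do not exclude them. A mixed split takes any difference between the groups as spread, which lowers its count. At unadjusted p under 0.05 by limma mixed splits reached 1364, and with unequal variances per probe set 22 passed in the real split. REG4, chosen after its values were seen, differed by 2.10 on the log2 scale. Skeletal muscle genes divided along the same line, with median 0.699 at 1 day and -0.0123 with ivermectin, each against uninjured. Whether the drug, its injection, a batch or the amount of surrounding tissue taken accounts for the pattern stays open.

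REG4, RGN and CDH17 rose most at 3 days, and tissue of another organ in the pools could raise them. Median changes at 3 days lay at percentile 76.7 of 10000 random lists for 12 kidney genes (5 higher, 3 lower), 39.2 for 11 intestinal genes (2 higher, 5 lower) and 97.4 for 21 liver genes (11 higher, 5 lower; median 0.157, unadjusted p = 0.156 by camera). The largest rises were 1.31, 0.816 and 2.25, against 5.81 for RGN. In uninjured arrays only 4 of the kidney and 3 of the intestinal genes lay between the lower and upper quartiles, the others being near background or so high that a small share of tissue would be hidden. These tissues cannot be told apart from a change within the cord, and all 3 stay open.

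Cell cycle genes were lower at 1, 3 and 7 days, and more muscle in the pools might dilute them. Against a dilution of all other cells alike, neuronal genes lay 1.08 above G2 and M phase genes at 1 day (95% interval 0.842 to 1.39). The intervals here come from resampling the genes of each list as if independent, and hold no spread between pools. An even loss of epidermal cells as the only cause is argued against at 1 day, where the epidermal list lay 0.594 above the G2 and M phase list (0.171 to 0.781). A loss of dividing epidermal cells alone need not lower the whole epidermal list as far, so it stays open at 1 day. At 3 days the gap was 0.0679 (-0.698 to 0.528) and at 7 days -0.43 (-0.873 to -0.08), so a loss of epidermal cells, dividing or not, stays open there.

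Each comparison was also refitted with its 6 arrays divided in all 10 ways. The real division gave the highest count in 1 of 10 each time: 10373, 11671 and 11193 probe sets at 1, 3 and 7 days against uninjured, 10680 for ivermectin against 1 day, 7797 and 7693 from 1 to 3 and from 3 to 7 days, and 861 for ivermectin against uninjured. The highest other count by limma was 0 in the first 6 and 2 in the last, with up to 314, 190, 214, 378, 558, 344 and 1364 at unadjusted p under 0.05. With 10 splits a share under 0.05 cannot be reached. The other splits mix the groups and take any difference between them as spread, which lowers their counts.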

How the results depend on the processing

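Genes instead of probe sets and median centring for gene lists were added only after the result was seen; the other settings were fixed earlier. For 552 results of named genes over all settings, 7693 values kept their call, 25 became weaker, 7 stronger and 0 reversed. Most of these genes were picked among the largest changes already called, so kept calls were likely beforehand and add little support. Over all probe sets, 7020 of the 10786 calls at 1 day against uninjured were shared with the test with unequal variances. For single lists, 1561 values stayed the same, 207 moved, 59 became stronger, 32 weaker and 1 reversed. All 207 that moved and the reversal came from leaving out 1 array, where 722 stayed the same. Of the weaker ones, 21 became so with an estimated correlation, 6 with cyclic loess and 4 with the mean of all probe sets of a gene. With a log2 change of at least 1, a stricter threshold, 1426, 2182 and 2104 probe sets passed at 1, 3 and 7 days, 1563 for ivermectin against 1 day, 788 from 1 to 3 days, 400 from 3 to 7 days and 32 for ivermectin against uninjured. With genes instead of probe sets, so fewer features, the counts were 4830, 5362, 5231, 5012, 3706, 3711 and 662 in the same order. A test per probe set with unequal variances, which borrows no spread from other probe sets, lowered the count in every comparison. At 1, 3 and 7 days against uninjured it gave 7195, 8522 and 8300, where the main fit gave 10786, 12016 and 11553. For ivermectin against 1 day it gave 7700, where the main fit gave 11024. It gave 4485 from 1 to 3 days, 3877 from 3 to 7 days and 22 for ivermectin against uninjured. That comparison had 861 with only its 6 arrays in the fit, and 904 (without uninjured replicate 2) to 1145 (without ivermectin replicate 1) when 1 array was left out. Scaling moved the share of rises among changed probe sets from 49.6% to 59.3% at 3 days (median centring), and the balance of rises and falls reversed under both other scalings at 1 and 3 days, for ivermectin against 1 day and from 3 to 7 days. A replicate block gave 10630, 11908, 11417, 10881, 7946, 7991 and 1229. With an estimated correlation 13 lists passed at 3 days and 9 from 3 to 7 days. The directional form of fry, which does not compare a list with other genes, gave 28 lists at 1 day, 27 at 7 days, 28 for ivermectin against 1 day, 27 from 1 to 3 days and 26 from 3 to 7 days. Its mixed form gave 31 lists in 6 comparisons and 28 for ivermectin against uninjured.

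In the skeletal muscle genes list, ivermectin 1 day post injury against uninjured, the median was -0.0123, and it was 0.00598 without uninjured replicate 3 and -0.0437 without uninjured replicate 1; the cause was not tested.

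The correlation of the ivermectin effect against injury effect was -0.968 with dim probe sets left out, -0.96549 without 1 day post injury replicate 1 and -0.96532 without 1 day post injury replicate 3.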

Other observations

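The lists for the tissue tests were written before those tests were run, and the genes named here were chosen after their values were seen.

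The Wnt, BMP and TGF-beta, and FGF and hedgehog lists were not called in any comparison, yet single members changed. At 7 days against uninjured the secreted Wnt modulators DKK3 rose by 2.02 ± 0.09 and SFRP2 by 1.44 ± 0.04. The ligand WNT2B (1.87 ± 0.07) and the receptor FGFR3 (2.04 ± 0.09) rose too, from low uninjured levels (3.87 and 4.63) that make these differences inexact. The growth factor carrier FGFBP1 changed by -2.73 ± 0.07 and the ligand BMP2 by -1.62 ± 0.09. These lists and the lymphocyte, ribosomal and xenobiotic lists passed in 0 of the 7 comparisons by camera in limma.

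REG4 was as high above uninjured with ivermectin (2.10 ± 0.08) as at 1 day (2.04 ± 0.08), while most 1 day changes were absent with ivermectin. Across the same comparisons, 245 probe sets were higher in both and 209 lower in both, where 152 and 226 would arise independently. More were opposite: 448 higher at 1 day and lower with ivermectin, and 261 lower and then higher, where 197 and 174 would arise independently. The changes correlated at -0.106 across probe sets, against a mean of 0.438 in simulations without effect, in which the shared uninjured arrays enter both. The simulated values ran from -0.421 to 0.935, so the observed correlation lies within their range.

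Of 11 measured intestinal epithelial genes, 5 lay at 11.01 (GPA33) to 12.88 (LGALS4) on the log2 scale in uninjured pools, and 6 lay at 3.35 (HNF4G) to 5.09 (FABP6), the transcription factor CDX2 among them (3.60). At 3 days the 5 abundant genes fell, EPCAM by 1.32 and LGALS4 by 0.70, and 2 of the other 6, DPP4 and ESPN, rose from levels near the lower quartile of the arrays. Of the genes in the tissue lists, the 31 fixed lists hold 0 of the kidney, 0 of the liver and 1 of the intestinal genes.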
